A study of Xenopus laevis with 74 samples.

How the data were processed

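The series holds 74 RNA-seq libraries of total RNA from Xenopus laevis embryos, 37 at developmental stage 18 and 37 at stage 30. Per the labels the source was presumptive neural tissue of the embryo, while the extraction notes speak of single embryos homogenised in TRI reagent. Which was sequenced could not be settled. Each stage has 8 groups: control, selfie control, and rotated, transplant and sham, each with a title number of 11 or 12. The design speaks of surgeries with a sibling control. The labels explain neither the title numbers nor the selfie control, and both are used here only as names.

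Per the labels the authors processed the reads with FastQC, HISAT2, SAMtools, HTSeq, kallisto and DESeq2. Versions, the genome build and the annotation are not given in the sources used here, so no chromosome positions are given. The deposited values are raw read counts per gene, in whole numbers, with 51065 gene entries per file. Xenopus laevis carries a long (.L) and a short (.S) copy of many genes, and these were kept apart. Of the entries, 1991 share 359 identifiers. These took 1.182% of all counts and were left out of the gene lists. In 72 files the closing HTSeq summary values are identical, equal to 29.29% to 148.1% of the gene counts, and 2 files (stage 30 sham 12 replicates 4 and 5) have none. They were not used. Kallisto output was not analysed here.

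Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Entries were kept by filterByExpr with its default settings, which left 31198 entries at stage 18, 33054 at stage 30 and 34604 over both stages. Library sizes were scaled by TMM. Each stage was fitted with 1 mean per group by the robust quasi-likelihood pipeline (trended dispersion), and comparisons across stages used a fit of all 74 libraries. P-values were adjusted by Benjamini and Hochberg over all entries tested, with a threshold of 0.05. Values per library are CPM (counts scaled to the TMM-adjusted library total), as mean ± SD. Log2 fold changes are given ± SE, with the numerator named first. All p-values are two-sided. Those of scores measure the spread between the libraries of the groups compared. Those of genes measure the spread of libraries within groups, estimated over all groups of the fit. Libraries outside a comparison therefore affect its calls.

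The comparisons were each surgery with control and with the sham of its number, rotated 11 with rotated 12, the rotated minus sham difference between the numbers, selfie control with control, the rotated minus control difference between stages, and control between stages. These 29 comparisons, the gene lists, the scores and the rule for named genes were fixed before the data were examined. The comparisons of sham with selfie control and of transplant with rotated, and the subtraction of the difference between selfie control and control, were chosen after seeing the data. Named genes are, for rotated against control or sham, the 10 with the largest change each way among those past the threshold with a mean log2 CPM of at least 1 and no overlap of groups, and the 5 largest each way for other comparisons. Genes known only by an identifier were counted but not named. Up to 4 members past the threshold were added for each list past its test, smallest p first, and a panel of 9 axial marker symbols (among them sox2, otx2, rax, six3, en2, egr2, hoxb9 and cdx4) was followed in every rotated comparison. The entries of sox2 share an identifier and were left out of it. For rotated and transplant against control and their stage differences, 92 of 94 genes named for the size of their change and all 18 list members are given. For the other comparisons 59 of 199 and 29 of 352 are given, and that choice was made after their values were seen. The remaining panel symbol and 1 other gene that the rule named are not reported here, though tests and counts over all genes or lists include them.

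The 29 gene lists cover the pan-neural state, forebrain and eye field, midbrain, hindbrain, posterior hox genes, tailbud and posterior signals, axis patterning signals, neuronal differentiation, neural crest, placodes and lens, photoreceptors, epidermis, multiciliated cells, ionocytes, cement and hatching gland, muscle, notochord, heart and endothelium, blood, macrophages, endoderm, pronephros, proliferation, immediate early response, stress and cell death, interferon and innate immunity, hypoxia and glycolysis, ribosomal proteins, and mitochondrially encoded transcripts. The 13 mitochondrial entries have a count of 0 in every library, so 28 lists were tested. Lists were tested against all other genes with camera (limma) at a preset correlation between genes of 0.01, adjusted over the 28 lists of a comparison. This preset is liberal where the genes of a list move together from embryo to embryo, so the p with the correlation estimated is also given, for single lists or as the lowest of a comparison. Each list was also adjusted over the list alone.

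2 planned values per library were scored from log2 CPM with a prior count of 2. The anterior-posterior balance is the mean of the forebrain and eye field list minus the mean of the posterior hox list. The developmental stage score is the mean of 7477 genes higher at stage 30 than at stage 18 in the selfie controls minus the mean of 3073 genes lower, each by at least 2-fold. Groups were compared by exact permutation tests, two-sided, adjusted over the 20 comparisons of the balance and the 12 of the stage score. Means of some lists per library, chosen after seeing the data, were tested likewise, each adjusted over 6 comparisons per stage. The smallest p these tests can give is 0.007937 for 5 against 5 libraries and 0.09524 for 2 against 5. These used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.

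Every count, except those of sham against selfie control and of the subtraction, was recomputed with RLE size factors, without the low-count filter, with a filter of a CPM of at least 1 in at least 5 libraries, with the title's replicate number as a block, with only the groups compared in the fit, with DESeq2 1.42.0, and with each library left out in turn. After seeing the data, fits without 3 libraries that stand apart (lists too) and without the 8 libraries of lowest total were added, and the neuronal list was tested with the stage score accounted for, at its change per unit of score between control stages. The 3 are stage 18 rotated 12 replicate 1 (low in muscle genes), stage 18 sham 12 replicate 5 (high in ribosomal protein genes) and stage 30 rotated 12 replicate 1 (high in inflammatory genes). The 8 are transplant 11 replicates 2 and 4 and transplant 12 replicates 4 and 5 of stage 18, and control replicates 4 and 5 and transplant 11 replicates 3 and 4 of stage 30. Lists were retested with an estimated correlation, the replicate block, RLE and the .L and .S copies summed. For each comparison 100 splits of its libraries, the real split among them, were drawn. No near-duplicates were found in 142 pairs of libraries of a group. In a simulation of stage 18 rotated 11 against control the pipeline found 69% of genes changed 2-fold and 98% of those changed 4-fold. It made 8 false calls among 175 and 0 when nothing was changed. Real libraries may differ.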

Results

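Embryos were compared by RNA-seq at stage 18 and stage 30 after surgeries labelled rotated, transplant and sham, numbered 11 or 12, and in controls. The series title names an anterior-posterior rotation. Library totals ranged from 8.5 to 42.9 M counts with a median of 29.4 M. The lowest were 8.5 M in transplant 11 and 9.6 M in transplant 12 at stage 18, and 8.9 M in control and 9.3 M in transplant 11 at stage 30. In every other group all lay between 21.7 and 42.9 M. Of the 51065 entries, 4456 had no count in any library. Groups hold 5 libraries and selfie control groups 2. Lists that involve the 3 libraries that stand apart were also tested without the 3. The estimated p of a list is its adjusted p with the correlation between genes estimated. Counts of list members past the threshold are given over all entries tested and then adjusted over the list alone. Where a list has p alone it had 0 members past both ways, except between the control stages and across the library sets described next.

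The libraries fell into 2 sets that cross the surgeries, 24 sham and selfie control and 50 control, rotated and transplant libraries. On the first principal component, which held 26.1% of the variance at stage 18, the sham and selfie control libraries lay between 36.2 and 148.6 and all others between -40.7 and 5.5. At stage 30 the component held 23.8%, with the sets at 40.3 to 66.7 and -39.0 to -7.6. Transcripts of rpl35a.L, which encodes a ribosomal protein, had a median of 74.9 CPM (31.0 to 139.7) in the 50 libraries. In 22 of the 24 sham and selfie control libraries they had a count of 0 (highest value 0.0941 CPM). This entry, which shares its identifier with another, was picked after its values were seen. The selfie controls carry no surgery in their labels and lay with the shams. Every comparison of a sham or selfie control group with a control, rotated or transplant group crosses these sets.

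**Figure D1:**
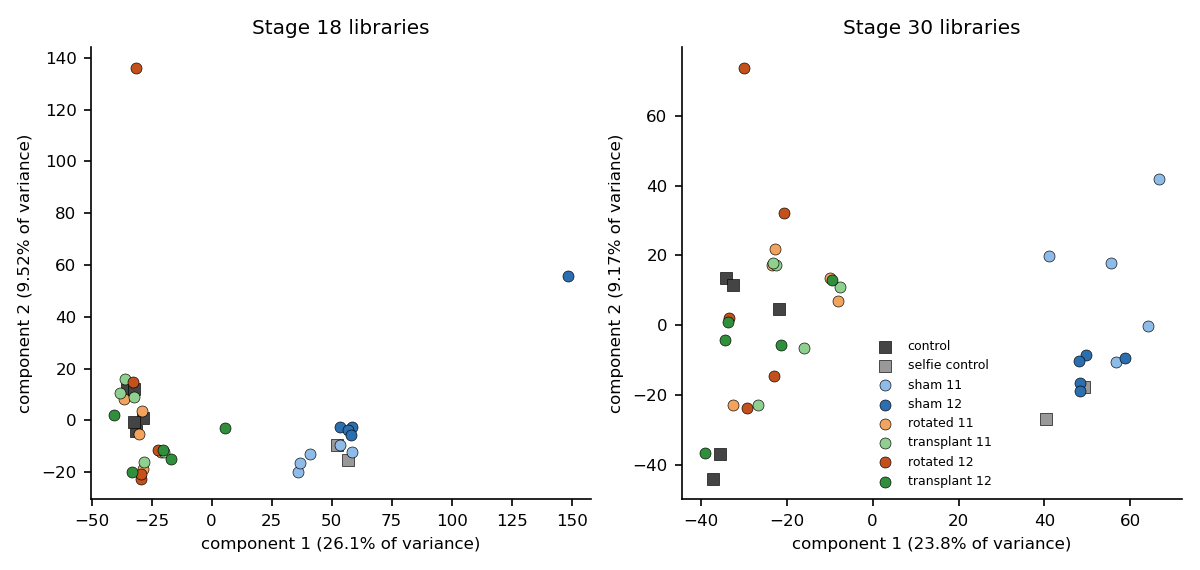
Scores of the 37 libraries of each stage on the first 2 principal components of log2 CPM (unitless axes, 1 point per library, colour by group).

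Controls were compared between stage 30 and stage 18. Transcripts of nefm.S (XB-GENE-6252136), a neurofilament subunit, were at 46.9 ± 5.57 CPM at stage 30 and 0.388 ± 0.114 CPM at stage 18 (SD, n = 5 each, 119-fold, adjusted p = 8.8e-30). The microtubule regulator stmn2.L rose 22.5-fold. The posterior homeobox genes cdx1.S and cdx4.L (XB-GENE-482791) fell 23.7-fold and 15.6-fold, cdx4.L from 112 ± 8.78 to 7.13 ± 1.78 CPM. Lens crystallin cryba1.S rose by 7.61 ± 0.49 on the log2 scale, the lipoprotein gene apob.S by 9.86 ± 0.93 and the globin hbd.S by 9.77 ± 1.15. The Nodal signalling cofactor foxh1.L changed by -6.02 ± 0.25 and the hyaluronan synthase has1.S by -6.28 ± 0.54. In all, 21081 entries differed, 12164 higher and 8917 lower at stage 30, and all 9 genes named here passed whichever library was left out.

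The neuronal differentiation list rose between the control stages (46 and 46 of 53 up, 0 and 1 down, camera adjusted p = 3.2e-13, estimated p of 0.0655). The tailbud and posterior signals list fell (24 and 26 of 29 down, adjusted p = 1.2e-14, estimated p of 0.0430), as did axis patterning signals (34 and 34 of 55 down, 8 and 8 up, adjusted p = 8.5e-07, estimated p of 0.0430). Heart and endothelium, macrophage, ribosomal protein, placode and muscle genes rose (adjusted p of at most 0.0443). Multiciliated cell (24 and 26 of 31 down, 2 and 3 up, 3.2e-05), proliferation (26 and 27 of 42 down, 6 and 6 up, 0.000140), epidermis, midbrain, notochord, pan-neural, forebrain and eye field, hindbrain and endoderm genes fell (at most 0.0277). These had an estimated p of 0.104 or higher. Endoderm was called lower with a median log2 change of -0.294 and a mean of 0.668.

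Rotated 11 embryos were compared with controls at stage 18. Among the higher genes were some of glutathione metabolism and redox defence. Transcripts of gstp1.L (XB-GENE-5846294), a glutathione S-transferase, were at 178 ± 44.6 against 4.83 ± 3.13 CPM (SD, n = 5 each, 36.9-fold, adjusted p = 0.0211). The glutathione synthesis gene gclc.S (XB-GENE-1002440) was at 17.01 ± 11.1 against 1.58 ± 0.413 CPM (adjusted p = 0.00878) and pir.L (XB-GENE-6256097), which encodes pirin, at 35.6 ± 13.02 against 3.66 ± 1.196 CPM (adjusted p = 0.0114). The peroxiredoxin prdx1.L rose by 1.25 ± 0.25 on the log2 scale and keap1.L, whose product marks the redox regulator Nrf2 for degradation, by 1.07 ± 0.20. The mitochondrial, hypoxia-inducible higd1a.S (XB-GENE-6256025) was at 52.3 ± 8.09 against 13.4 ± 5.73 CPM (adjusted p = 0.000244). The mitochondrial transporter abcb6.L (1.85 ± 0.30), the cytokine-activated factor stat3.2.L (1.12 ± 0.17), fah.L of tyrosine breakdown (1.44 ± 0.31) and lonrf3.S (1.02 ± 0.22) were also higher.

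Some neuronal and eye genes were lower in rotated 11 at stage 18. The neuronal intermediate filament prph.L (XB-GENE-866295) was at 33.6 ± 4.42 against 73.7 ± 3.96 CPM (SD, n = 5 each, adjusted p = 0.000812). The visual system homeobox gene vsx1.L (XB-GENE-866467) was at 2.79 ± 1.76 against 9.56 ± 2.43 CPM (adjusted p = 0.0108), and the eye-field Wnt receptor fzd5.S changed by -0.94 ± 0.18 on the log2 scale. The glutamate transporter slc1a1.S (-1.26 ± 0.26), ankrd27.L (-0.68 ± 0.14) and the autophagy gene rb1cc1.L (-0.64 ± 0.12) were also lower. The forebrain and eye field list fell, with 29 of 41 members negative and a median of -0.330 (1 and 8 of 41 down, adjusted p = 3.9e-07, estimated p of 0.630). None of the 12 panel entries given here passed. The eye-field gene rax.L was at 35 ± 19.5 against 63.8 ± 7.80 CPM (log2 change -0.87 ± 0.28, adjusted p = 0.290) and rax.S changed by -1.13 ± 0.37 (adjusted p = 0.280). The log2 change was -0.64 ± 0.26 for six3.S, 0.05 ± 0.14 for otx2.L, 0.09 ± 0.18 for hoxb9.S and 0.18 ± 0.16 for cdx4.L.

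In rotated 11 at stage 18 lists that rose were tailbud (adjusted p = 5.1e-05), axis patterning (2 and 5 of 54 up, 4.7e-05), neural crest (0 and 10 of 38 up, 1.9e-06), hindbrain (0.0437) and immediate early genes (0 and 1 of 48 up, 0 and 1 down, 0.0417). Both axis members past the threshold handle retinoic acid. The gene rdh10.L, whose product makes its precursor, rose by 0.41 ± 0.07 and cyp26a1.L, whose product degrades it, by 0.69 ± 0.15. Neuronal differentiation (1 and 4 of 52 down, 0.000543), macrophage (0.000380) and ribosomal protein genes (3.9e-07) fell. By estimated p no list passed, the lowest being 0.227.

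The test called 34 entries, 23 higher and 11 lower, 9 without a symbol. Without the 3 libraries that stand apart, none of them in either group compared, it called 166. Of the 18 named genes 6 passed whichever library was left out, namely abcb6.L, gclc.S, higd1a.S, prph.L, rdh10.L and stat3.2.L. The count was 84 without rotated 11 replicate 2, 22 and 21 without its replicates 1 and 5, and 22, 17 and 20 without control replicates 2, 3 and 5.

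**Figure D2:**
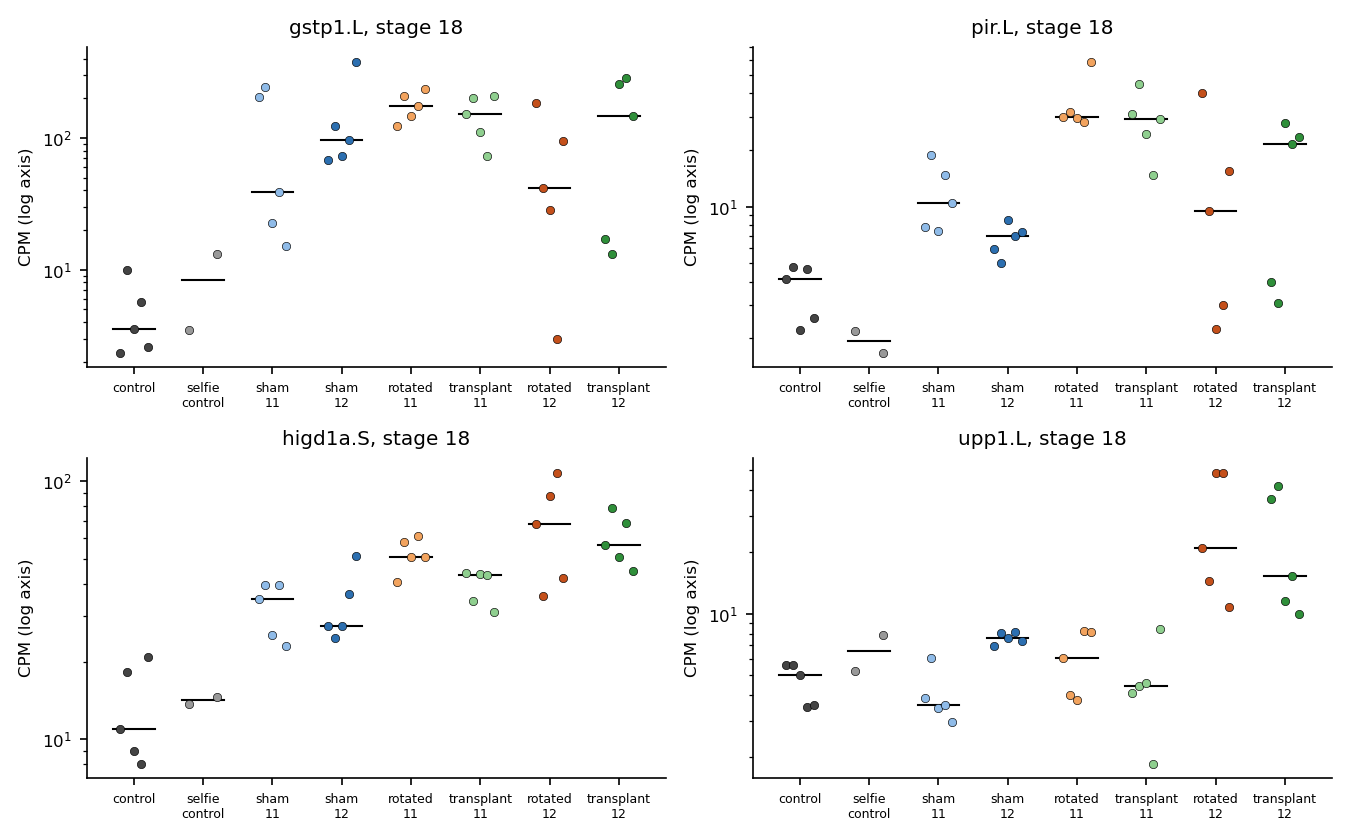
CPM (log axis) of gstp1.L, pir.L, higd1a.S and upp1.L in each stage 18 library, 1 point per library with a line at each group median.

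**Figure D3:**
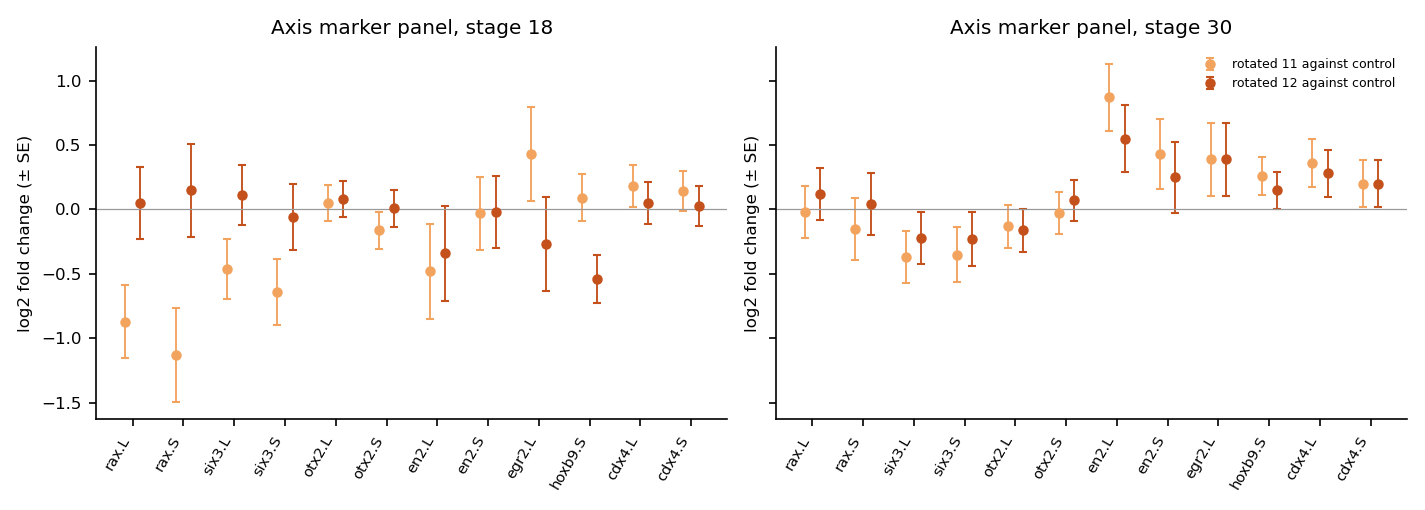
Log2 fold change against control ± SE (n = 5 each) of 12 panel entries in rotated 11 and rotated 12 at both stages. None passed the threshold of 0.05.

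Transplant 11 embryos were compared with the same stage 18 controls. Transcripts of gstp1.L were at 149 ± 57.9 against 4.83 ± 3.13 CPM (SD, n = 5 each, adjusted p = 0.0476), pir.L at 28.7 ± 10.9 against 3.66 ± 1.196 CPM (adjusted p = 0.0476) and higd1a.S at 39.4 ± 6.16 against 13.4 ± 5.73 CPM (adjusted p = 0.00851). Also higher were abcb6.L (1.51 ± 0.30 on the log2 scale), lonrf3.S (1.32 ± 0.22) and rdh10.L (0.37 ± 0.07), and prph.L was lower at 40.5 ± 9.14 against 73.7 ± 3.96 CPM (adjusted p = 0.0410). Proliferation (0 and 1 of 42 up, adjusted p = 1.4e-05), axis patterning (1 and 5 of 54 up, 6.0e-05), tailbud (6.0e-05), neural crest (0 and 8 of 38 up, 0.000362), pan-neural (0 and 2 of 23 up, 0.0298) and immediate early genes (0 and 6 of 48 up, 0 and 1 down, 0.0298) rose. Neuronal differentiation (1 and 6 of 52 down, 6.0e-05), ionocyte (0.0116) and ribosomal protein genes (6.0e-08) fell. No list passed by estimated p (lowest 0.276).

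For transplant 11 the test called 16 entries, 15 higher and 1 lower. Without the 3 libraries that stand apart, none of them in either group compared, it called 343. Of the 7 named genes only lonrf3.S passed whichever library was left out. The count was 155, 10, 6, 10 and 10 without transplant 11 replicates 1 to 5, and 6, 9 and 3 without control replicates 1, 2 and 4. DESeq2 called 223, 65.9% of them higher (93.8% here).

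Rotated 12 embryos at stage 18 were compared with the same controls. The pyrimidine salvage gene upp1.L (XB-GENE-17331934) was at 28.6 ± 18.6 against 4.68 ± 1.05 CPM (SD, n = 5 each, adjusted p = 0.00183), higd1a.S at 68.3 ± 30.3 against 13.4 ± 5.73 CPM (adjusted p = 1.7e-05) and stat3.2.L at 31.5 ± 5.29 against 12.51 ± 1.39 CPM (adjusted p = 3.6e-05). The collagen prolyl hydroxylase p4ha2.L rose by 1.26 ± 0.27, the pyruvate dehydrogenase kinase pdk3.L by 1.54 ± 0.33 and the glycolytic enzyme pgam1.S by 1.73 ± 0.38. So did tmem37.S (1.86 ± 0.34), the epithelial factor elf3.S (1.60 ± 0.37), tspan15.S (1.53 ± 0.32) and the fatty acid desaturase fads1.S (1.34 ± 0.27). The muscle phosphoglycerate mutase pgam2.L (XB-GENE-6254944) was at 3.61 ± 2.09 against 20.5 ± 3.96 CPM (adjusted p = 0.00875). Also lower were the ATP synthase genes atp5a1.S (-0.55 ± 0.12) and atp5a1.L (-0.51 ± 0.12), shmt2.L of folate metabolism (-0.68 ± 0.13) and the tRNA synthetases qars.L (-0.71 ± 0.16) and aars2.L (-0.60 ± 0.13). So were ywhag.S (-1.09 ± 0.26), cers3.L (-0.88 ± 0.21), tmem206.L (-0.81 ± 0.18) and scamp3.L (-0.74 ± 0.17).

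The muscle list fell in rotated 12 at stage 18, with 36 of 39 members negative and a median of -0.482 (0 and 3 of 39 down, adjusted p = 1.5e-15). Neuronal, posterior hox, ribosomal protein and pan-neural (adjusted p of at most 0.0295) and notochord (0 and 0 of 28 down, 0 and 1 up, 0.0182) genes also fell. Immediate early genes rose (2 and 8 of 48 up, 0 and 3 down, 0.0188), among them fosl1.L (3.90 ± 0.76), part of the AP-1 factor, and the cytokine signalling inhibitor socs3 (1.91 ± 0.41). Their mean per library passed no exact permutation test at either stage (lowest adjusted p = 0.1905). Epidermis (0 and 2 of 31 up, 0 and 1 down), endoderm (1 and 4 of 30 up) and heart genes (1 and 2 of 36 up) rose (at most 0.0295), the endoderm and heart call being gata6.L (0.71 ± 0.16). No list passed by estimated p (lowest 0.491). Without the 3 libraries only muscle, immediate early and ribosomal protein genes still passed (at most 0.0138), and pan-neural genes were higher instead (0.0218). In the panel rax.L (0.05 ± 0.28) and rax.S (0.15 ± 0.36) did not pass.

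For rotated 12 at stage 18 the test called 109 entries, 83 higher and 26 lower, 41 without a symbol. Of the 23 named genes higd1a.S, pgam2.L, stat3.2.L and upp1.L passed whichever library was left out. The count was 319, 39 and 34 without rotated 12 replicates 2, 3 and 4, and 23, 21, 16, 33 and 38 without control replicates 1 to 5.

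Transplant 12 embryos at stage 18 were higher than controls in gstp1.L, at 143 ± 128 against 4.83 ± 3.13 CPM (SD, n = 5 each, adjusted p = 0.0176), higd1a.S, at 59.9 ± 13.7 against 13.4 ± 5.73 CPM (adjusted p = 5.2e-05), and upp1.L, at 22.9 ± 14.9 against 4.68 ± 1.05 CPM (adjusted p = 0.00540). The cytochrome P450 gene cyp2d6.S rose by 2.86 ± 0.49 and the heme-binding protein gene hebp2.L by 3.16 ± 0.75. The Piwi family gene piwil3.L was lower at 0.754 ± 0.152 against 5.09 ± 1.19 CPM (adjusted p = 0.0332), as were c14orf166.S (-1.34 ± 0.31), pde4dip.S (-1.16 ± 0.28), awat1.L (-1.15 ± 0.28) and the dipeptidase cndp1.L (-1.12 ± 0.27). Immediate early genes rose (2 and 9 of 48 up, 0 and 1 down, adjusted p = 0.0186), among them fos.S (1.80 ± 0.32) and fosl1.L (3.36 ± 0.77). Multiciliated cell (4.3e-05), neural crest (1 and 1 of 38 up, 0.0175, through the complement gene c9.L at 1.65 ± 0.30), axis patterning (0.0439) and epidermis genes (1 and 3 of 31 up, 0.0476, through the keratin krt8.S at 0.38 ± 0.09) rose. Ribosomal protein (9.3e-08), macrophage (0.00407) and muscle genes (0 and 1 of 39 down, 0.00658) fell. By estimated p none passed (lowest 0.483).

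For transplant 12 at stage 18 the test called 169 entries, 118 higher and 51 lower, 59 without a symbol. Of the 14 named genes c9.L, cyp2d6.S, fos.S, higd1a.S and upp1.L passed whichever library was left out. The count was 304, 75, 100, 84 and 77 without transplant 12 replicates 1 to 5, and 68, 38, 56, 87 and 92 without control replicates 1 to 5.

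Against rotated 12 at stage 18, rotated 11 was higher in muscle (34 of 39 positive, adjusted p = 3.8e-16), posterior hox (31 of 36 positive, 2.0e-12), tailbud, axis patterning (0 and 3 of 54 up, 0 and 1 down), hindbrain (0 and 1 of 29 up), pan-neural, midbrain, neural crest and notochord genes (at most 0.00644). It was lower in forebrain and eye field (0 and 6 of 41 down, 0.000995), macrophage, cement gland (0 and 5 of 10 down), epidermis, heart and endoderm genes (at most 0.00594). Without the 3 libraries only muscle, posterior hox and forebrain and eye field still passed (at most 0.0109). The lowest estimated p was 0.337. With edgeR 0 entries passed, 2762 had an unadjusted p below 0.05, and DESeq2 called 64. The count was 3, 3 and 8 without rotated 12 replicates 1, 2 and 5, and 1 and 3 without rotated 11 replicates 2 and 4.

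At stage 18 transplant 11 was higher than rotated 11 in forebrain and eye field (0 and 7 of 41 up, adjusted p = 1.3e-09, estimated p of 0.676) and proliferation genes (34 of 42 positive, 0.000191 and 0.676). Transplant 12 was higher than rotated 12 in multiciliated cell (26 of 31 positive, adjusted p = 0.000563, estimated p of 0.477) and lower in ribosomal protein genes (85 of 110 negative, 0.0171 and 0.762). Its other calls, muscle, posterior hox and macrophage genes among them, did not pass without the 3 libraries (at least 0.230 for these). With edgeR 0 entries passed for either number, against 817 (11) and 1847 (12) at an unadjusted p below 0.05 and 5 and 6 by DESeq2. Without rotated 11 replicate 4 the first count was 1.

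Sham embryos at stage 18 were compared with control, across the 2 library sets. Transcripts of gstp1.L were at 105 ± 110.2 CPM in sham 11 and 148 ± 131 CPM in sham 12, against 4.83 ± 3.13 CPM in control (SD, n = 5 each, adjusted p = 0.00175 and 0.000435). The uridine kinase gene uck1.S was at 49.0 ± 5.04 and 46.5 ± 3.25 against 5.34 ± 0.657 CPM, and the mitotic kinase plk1.S rose by 0.82 ± 0.14 and 0.83 ± 0.14. In sham 11 the retinoid genes rdh10.L (0.59 ± 0.07) and cyp26a1.L (1.21 ± 0.15) rose, and the ribosomal protein gene rps29.S (-3.08 ± 0.40) and lin7c.L (-2.86 ± 0.39) fell. In sham 12 the chaperone gene hsp90aa1.1.L rose (4.18 ± 0.90), and soat1.L of cholesterol esterification (-3.46 ± 0.40) and rps21.L (-3.02 ± 0.55) fell. Selfie control (n = 2) was also higher than control in uck1.S (3.18 ± 0.62), hsp90aa1.1.L (3.10 ± 0.98) and plk1.S (0.73 ± 0.18), and lower in rps21.L (-3.73 ± 0.84), soat1.L (-3.24 ± 0.58) and rps29.S (-2.94 ± 0.59).

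Proliferation genes rose against control in sham 11 (17 and 20 of 42 up), sham 12 and selfie control (adjusted p of at most 0.0140). Sham 11 was higher in axis patterning, endoderm, posterior hox and immediate early genes (at most 0.0178). Multiciliated cell genes rose in sham 12 (22 and 23 of 31 up, 2 and 3 down) and selfie control (at most 0.000289), ribosomal protein genes in sham 12 (0.0300, 0.116 and lower without the 3 libraries) and neuronal genes in selfie control (0.00693). The lowest estimated p was 0.209, 0.394 and 0.992 in the 3 comparisons. The counts were 5691 for sham 11 (2782 higher), 9132 for sham 12 (4529 higher) and 2489 for selfie control (1254 higher). The last was 655 and 251 without its replicates 1 and 2, and of its 6 named genes only uck1.S passed whichever library was left out.

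Within the set, sham and selfie control embryos of stage 18 differed in 10 entries for sham 11 (3 higher) and 2 for sham 12. Sham 11 was higher in rdh10.L (0.58 ± 0.10) and lower in lin7c.L (-2.77 ± 0.45) and the isoprenoid synthesis gene fdps.L (4.21 ± 0.691 against 37.2 ± 1.22 CPM, n = 5 and 2, edgeR adjusted p = 0.000657). Immediate early genes were higher than in selfie control in both shams (adjusted p = 0.00729 and 0.00760, estimated p of 0.218 and 0.180). Posterior hox genes were higher in sham 11 (36 of 36 positive, adjusted p = 2.1e-08, estimated p of 0.514) and ribosomal protein genes in sham 12 (107 of 110 positive, adjusted p = 3.1e-10, estimated p of 0.916), though these were lower without the 3 libraries (0.0465).

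Rotated and transplant embryos were compared with the sham of their number at stage 18, which also crosses the library sets. Rotated 11 was higher in rps29.S (2.98 ± 0.40), lin7c.L (2.88 ± 0.39) and the ascorbate transporter slc23a2.L (112 ± 10.3 against 23.2 ± 1.53 CPM, SD, n = 5 each, adjusted p = 6.9e-12), and lower in uck1.S (-2.24 ± 0.52), gata5.S of the endoderm (-0.96 ± 0.20) and prph.L (-0.86 ± 0.17). Rotated 12 was higher in soat1.L (3.84 ± 0.40) and rps21.L (3.23 ± 0.55) and lower in uck1.S (-2.05 ± 0.52), rpl3.L (-0.64 ± 0.10) and the chaperone genes hsp90aa1.1.L (-2.40 ± 0.83) and hsph1.S (-2.22 ± 0.58). Transplant 11 differed in rps29.S (2.88 ± 0.40), lin7c.L (2.70 ± 0.39) and uck1.S (-3.43 ± 0.56), and transplant 12 in soat1.L (3.39 ± 0.40), rps21.L (3.05 ± 0.55), uck1.S (-3.20 ± 0.55) and the myeloid factor spib.L (-1.99 ± 0.42). Of the panel, cdx4.L was higher in rotated 11 (0.77 ± 0.17, adjusted p = 0.00190) and rotated 12 (0.86 ± 0.17, 0.000211). In rotated 12 the hsp90aa1.1.L call was lost in 4 of 10 fits that left out 1 library.

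Neuronal genes were lower than sham in rotated 11, transplant 11, rotated 12 (17 and 17 of 52 down) and transplant 12 (adjusted p of at most 0.00305) at stage 18, and so were proliferation genes (at most 0.0294). Endoderm fell in rotated 11 and transplant 11 (0.00274 and 0.0294) and forebrain and eye field in both rotated groups (0.0134 and 0.0102). Ribosomal protein, multiciliated cell and blood genes (at most 0.0196) fell in rotated 12 and transplant 12, muscle (0.000127) and notochord (0.0254) in rotated 12, and macrophages (0.000190) in transplant 12. Of the rotated 12 calls, forebrain, ribosomal protein, muscle and notochord failed without the 3 libraries (at least 0.307). Those of transplant 12 all passed (at most 0.0469), the ribosomal median going from -0.470 to -0.094. The lowest estimated p of the 4 comparisons was 0.452.

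The counts against sham at stage 18 were 3943 for rotated 11 (2213 higher), 4337 for transplant 11 (2384), 9206 for rotated 12 (4918) and 7561 for transplant 12 (3912). With only the groups compared the last 2 were 3864 and 3736, without the 3 libraries the first 2 were 6400 and 6984, and without the 8 of lowest total transplant 11 had 2790. Of the calls 95.9%, 94.8%, 95.2% and 93.6% had the direction of control against selfie control.

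The rotated minus sham difference was compared between numbers 11 and 12 at stage 18. The isoprenoid gene fdps.L was the named gene (2.86 ± 0.53, adjusted p = 0.0393), lost in 13 of the 20 fits that each left out 1 library. The difference was higher for 11 in multiciliated cell (0 and 10 of 31 up, adjusted p = 5.3e-11), ribosomal protein, muscle, neuronal, pan-neural and tailbud genes (at most 0.0435), and lower in heart (0 and 3 of 36 down, 0 and 1 up) and endoderm genes (0 and 1 of 30 down, at most 0.00842). Only multiciliated cell genes still passed without the 3 libraries (1.8e-09). No list passed by estimated p (lowest 0.482). The test called 4 entries, 1 higher and 3 lower, and DESeq2 93. The count was 33, 30 and 2 without sham 11 replicates 1, 2 and 5, 9 and 15 without rotated 12 replicates 3 and 5, 7, 2 and 2 without sham 12 replicates 2 to 4, and 2 without rotated 11 replicate 2, 3 or 4.

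Rotated 11 embryos at stage 30 were compared with controls. Both copies of gad1.1, which encodes an enzyme of GABA synthesis, were lower, gad1.1.S at 5.79 ± 1.37 against 11.7 ± 1.94 CPM and gad1.1.L at 9.59 ± 1.93 against 17.6 ± 3.49 CPM (SD, n = 5 each, adjusted p = 0.0381 each). The vesicular acetylcholine transporter slc18a3.S was at 2.01 ± 0.678 against 4.81 ± 0.707 CPM and the synaptic complexin cplx1.L (XB-GENE-5815666) at 8.28 ± 2.34 against 19.0 ± 2.40 CPM (adjusted p = 0.0381 and 0.0379). The purine synthesis gene paics was higher (0.53 ± 0.10, adjusted p = 0.0381). Of the neuronal differentiation list 47 of 53 members were negative, with a median of -0.310 (1 and 21 of 53 down, adjusted p = 5.6e-19, estimated p of 0.0834). Its mean log2 CPM was 3.45 ± 0.10 in rotated 11 and 3.76 ± 0.13 in control (SD, n = 5 each, exact permutation test, adjusted p = 0.0318), with all 5 rotated libraries below every control. Proliferation (adjusted p = 1.0e-05), posterior hox (0.000117), tailbud (0 and 2 of 28 up, 0.000355), axis patterning (0.0326) and notochord genes (0.0470) rose, with an estimated p of 0.253 or higher. In the panel rax.L (-0.02 ± 0.20), rax.S (-0.15 ± 0.24) and en2.L of the midbrain-hindbrain boundary (0.87 ± 0.26, adjusted p = 0.209) did not pass.

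For rotated 11 at stage 30 the test called 11 entries, 2 higher and 9 lower, 4 without a symbol. Of the 5 named genes 0 passed whichever library was left out. The count was 0 without control replicate 1, 3 or 4 or rotated 11 replicate 1 or 3, 2 and 33 without rotated 11 replicates 2 and 4, and 6 and 7 without control replicates 2 and 5.

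**Figure D4:**
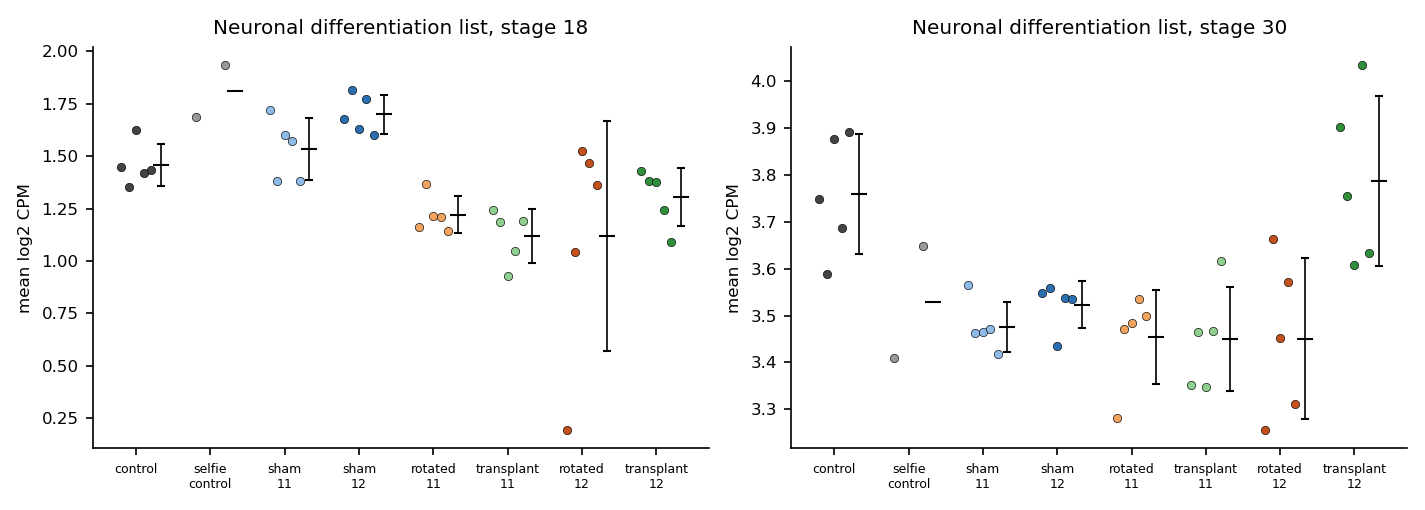
Mean log2 CPM of the neuronal differentiation list in each library of both stages, 1 point per library, with bars at the group mean ± SD (selfie control, n = 2, mean only).

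Transplant 11 embryos at stage 30 were compared with the same controls and were lower in neuronal genes, with 48 of 53 members negative and a median of -0.354 (0 and 15 of 53 down, adjusted p = 3.4e-18, estimated p of 0.0994). The list averaged 3.45 ± 0.11 against 3.76 ± 0.13 log2 CPM (SD, n = 5 each, exact permutation test, adjusted p = 0.0318), with 4 of 5 libraries below every control. Forebrain and eye field, photoreceptor and heart genes fell (adjusted p of at most 0.0210). Proliferation (4.9e-05), posterior hox (0.000391), tailbud, epidermis and axis patterning genes rose (at most 0.0272). The other lists had an estimated p of 0.506 or higher. With edgeR 0 entries passed, 3273 had an unadjusted p below 0.05, and DESeq2 called 105. The count was 1 without control replicate 1, 2 or 5 or transplant 11 replicate 1, and 2 without transplant 11 replicate 5.

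Rotated 12 embryos at stage 30 were higher than controls in some inflammatory genes, mainly through replicate 1. The neutrophil collagenase mmp8.L was at 196 ± 438 against 0.244 ± 0.260 CPM (SD, n = 5 each, adjusted p = 0.0324), with 981 CPM in replicate 1 and at most 1.06 CPM in the other 4. The chemokine cxcl8.S (8.85 ± 1.90), the gelatinase mmp9.L (6.86 ± 1.49), socs3.L (3.81 ± 0.84) and socs3-like.1.L (1.98 ± 0.48) were also higher. Also higher were cth.L of cysteine synthesis (189 ± 38.8 against 130.5 ± 17.7 CPM, with 258 CPM in replicate 1 and at most 175 in the other 4), gstz1.L (0.92 ± 0.21), stard4.L (0.88 ± 0.20), cyp2d6.S (0.77 ± 0.19), sat1.L of polyamine breakdown (0.67 ± 0.14) and dbi.S (0.64 ± 0.15). So were the leukocyte tetraspanin cd37.S (0.75 ± 0.16), twf1.S (0.54 ± 0.11), anapc13.1.L (0.52 ± 0.12) and ddit4.S of the stress list (0.42 ± 0.10). The neurofilament gene nefm.L (XB-GENE-6252137) was at 49.0 ± 10.1 against 74.6 ± 5.5 CPM (adjusted p = 0.0324). Other neuronal genes were lower, namely the synuclein sncb.S (-0.54 ± 0.13), sez6l2.L (-0.62 ± 0.13), sez6l2.S (-0.72 ± 0.17), dpysl5.S (-0.64 ± 0.13) and the prohormone convertase pcsk2.L (-0.64 ± 0.14). So were the mechanosensitive channel piezo1.L (-0.97 ± 0.21), lrrc3c.S (-0.92 ± 0.20), ganc.L (-0.78 ± 0.18), meis2.S (-0.71 ± 0.18) and osbp2.L (-0.61 ± 0.15).

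The neuronal list fell in rotated 12 at stage 30, with 49 of 53 members negative and a median of -0.310 (2 and 16 of 53 down, adjusted p = 1.2e-15, estimated p of 0.191). It averaged 3.45 ± 0.17 log2 CPM (SD, n = 5, exact permutation test against control, adjusted p = 0.0318), with 4 of 5 libraries below every control. Ribosomal protein (0 and 17 of 110 up, 2.2e-17), immediate early (8 and 27 of 48 up, 0 and 1 down), stress (1 and 7 of 36 up) and cement gland genes (0 and 1 of 10 up) rose (at most 0.0183). Hindbrain, muscle and multiciliated cell genes fell (at most 0.0448). Their estimated p was 0.334 or higher. Without the 3 libraries immediate early, stress and hindbrain genes did not pass (at least 0.0800) and the others did (at most 0.0212).

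For rotated 12 at stage 30 the test called 203 entries, 154 higher and 49 lower, 64 without a symbol. Of the 26 named genes 0 passed whichever library was left out. The count was 0 without rotated 12 replicate 1 or any of control replicates 1 to 4, 987 without control replicate 5, and 368 and 889 without rotated 12 replicates 2 and 4.

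Transplant 12 embryos at stage 30 did not differ detectably from control in neuronal genes, with a list mean of 3.79 ± 0.18 against 3.76 ± 0.13 log2 CPM (SD, n = 5 each, exact permutation test, adjusted p = 0.924). Ribosomal protein (107 of 110 positive, adjusted p = 6.1e-16), proliferation (8.0e-05), forebrain and eye field (36 of 42 positive, 0.000564), pan-neural, photoreceptor and neural crest genes rose (at most 0.0467). Epidermis, blood, hypoxia and glycolysis and multiciliated cell genes fell (at most 0.0498). No list passed by estimated p (lowest 0.763), and epidermis was called lower with a median of -0.0850 and a mean of 0.005. With edgeR 0 entries passed, 2564 had an unadjusted p below 0.05, and DESeq2 called 50. The count was 37 without control replicate 5 and 1 without transplant 12 replicate 2.

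Compared directly with rotated 12 at stage 30, transplant 12 was higher in the neuronal list, with 51 of 53 members positive (0 and 4 of 53 up, adjusted p = 2.6e-19, estimated p of 0.0776), as were forebrain and eye field (38 of 42 positive, 2.0e-08), pan-neural (0 and 6 of 23 up, 5.4e-07) and muscle genes (30 of 41 positive, 4.5e-05). Blood genes were lower (22 of 23 negative, 5.8e-05), as were immediate early (1 and 27 of 48 down) and stress genes (at most 0.000539), but these last 2 did not pass without the 3 libraries (at least 0.121) and the others did (at most 0.00119). Their estimated p was 0.275 or higher. The test called 7 entries (2 higher, 5 lower), among them the protocadherin pcdh10.L (0.81 ± 0.16), dcaf7.S (0.34 ± 0.06) and socs3.L (-4.71 ± 0.87). The count was 0 without transplant 12 replicate 1, 2, 3 or 4 or rotated 12 replicate 1, 1 without transplant 12 replicate 5, and 206, 88, 193 and 95 without rotated 12 replicates 2 to 5. Transplant 11 was lower than rotated 11 in midbrain (0 and 1 of 25 down, 0.00760) and higher in endoderm genes (27 of 34 positive, 0.0101, estimated p of 0.701 for both), with 0 entries past by edgeR, 890 at an unadjusted p below 0.05 and 0 by DESeq2.

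Rotated 11 at stage 30 was lower than rotated 12 in ribosomal protein (0 and 17 of 110 down, adjusted p = 7.8e-18), immediate early (0 and 22 of 48 down), interferon (0 and 3 of 24 down), stress, endoderm, blood and heart genes (at most 0.0285). It was higher in posterior hox (0.000783), epidermis (0 and 1 of 33 up, 0.00144), notochord, proliferation, multiciliated cell, hindbrain and pan-neural genes (at most 0.0465). Without the 3 libraries immediate early genes were higher instead (0.0256) and interferon, stress, proliferation, hindbrain and pan-neural genes did not pass (at least 0.0626). The lowest estimated p was 0.534. With edgeR 0 entries passed, 4267 had an unadjusted p below 0.05, and DESeq2 called 418. The count was 95, 181, 518 and 171 without rotated 12 replicates 2 to 5 and 8 without rotated 11 replicate 2.

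Sham and selfie control were compared with control at stage 30, across the library sets. Cardiac actin actc1.S was at 1840 ± 209 CPM in sham 11, 1722 ± 242 in sham 12 and 1732 ± 31.2 in selfie control (n = 2), against 789 ± 219 CPM in control (SD, n = 5 otherwise, edgeR adjusted p = 0.000105, 0.000299 and 0.00893). The migrating-neuron gene dcx.L was lower (-1.65 ± 0.19, -1.50 ± 0.19 and -0.99 ± 0.25) and the keratin krt5.7.S higher (0.59 ± 0.11, 0.46 ± 0.11 and 0.48 ± 0.14). Sham 11 was lower in lrrc59.L (-2.04 ± 0.18) and the ceramide synthase cers6.S (-1.99 ± 0.23). Sham 12 was lower in lrrc59.L (-2.16 ± 0.18) and smad4.1.S (-2.37 ± 0.53) and higher in the mitochondrial channel gene vdac3.S (1.69 ± 0.19), and selfie control differed in smad4.1.S (-2.45 ± 0.77) and vdac3.S (1.75 ± 0.23).

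Proliferation, ribosomal protein, muscle and epidermis genes rose against control in sham 11, sham 12 and selfie control (adjusted p of at most 0.0251). Neuronal genes fell in all 3 (18 and 18 of 53 down, 1 and 1 up in sham 11, at most 0.0354). Notochord rose in both shams (0.0381 and 0.0241), posterior hox in sham 11 and selfie control (0.00172 and 0.00676), and multiciliated cell and axis patterning genes (at most 0.0184) in sham 11. By estimated p the lowest value was 0.663. The counts were 9445 for sham 11 (4610 higher), 8380 for sham 12 (4068) and 2677 for selfie control (1251), the last being 380 and 759 without its replicates 1 and 2. All genes named for the shams passed whichever library was left out, and of the 5 named for selfie control only vdac3.S. Sham and selfie control differed in 1 entry for sham 11 and, with edgeR, 0 for sham 12 (1305 at an unadjusted p below 0.05).

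Rotated and transplant embryos at stage 30 were compared with their shams, across the library sets. Rotated 11 was higher in lrrc59.L (1.88 ± 0.17), cers6.S (1.97 ± 0.23) and slc23a2.L (71.0 ± 4.50 against 19.7 ± 3.22 CPM, SD, n = 5 each, adjusted p = 7.8e-13), and lower in vdac3.S (-1.37 ± 0.19) and actc1.S (-1.01 ± 0.22). Rotated 12 was higher in smad4.1.S (2.41 ± 0.53) and lrrc59.L (2.33 ± 0.18) and lower in vdac3.S (-1.74 ± 0.19), otog.L (-1.67 ± 0.30) and actc1.S (-1.39 ± 0.22). Transplant 11 differed in cers6.S (2.18 ± 0.23), vdac3.S (-1.67 ± 0.19) and actc1.S (-1.12 ± 0.22), and transplant 12 in smad4.1.S (2.77 ± 0.54), dcx.L (1.49 ± 0.18), vdac3.S (-1.75 ± 0.19) and actc1.S (-1.16 ± 0.22). In the panel cdx4.L was higher in rotated 11 (0.63 ± 0.18, adjusted p = 0.0122) and rotated 12 (0.63 ± 0.18, 0.00934), and en2.L higher in rotated 11 (0.91 ± 0.26, 0.01004). The cdx4.L call in rotated 12 was lost in 1 of 10 fits that left out 1 library.

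Proliferation, muscle and multiciliated cell genes fell against sham in rotated 11, transplant 11, rotated 12 and transplant 12 at stage 30 (adjusted p of at most 0.0198). Ribosomal proteins fell in rotated 11 and transplant 11 (at most 1.7e-06), epidermis in rotated 11 (0.0465), rotated 12 (0.00172) and transplant 12 (3.2e-05), and notochord in rotated 12 (0.00284) and transplant 12 (0.0369). Hindbrain fell in rotated 12 (0.00854, 0.0859 without the 3 libraries), blood in transplant 12 (0.0307), and forebrain (0.0215) and immediate early genes (0.0334) in transplant 11, while neuronal genes rose in transplant 12 (12 and 16 of 53 up, 0 and 1 down, 0.00882). The lowest estimated p of the 4 comparisons was 0.430. The counts were 6669 for rotated 11 (3646 higher), 5951 for transplant 11 (3161), 8670 for rotated 12 (4695) and 7515 for transplant 12 (4031), of which 95.8%, 96.2%, 93.2% and 96.1% had the direction of control against selfie control.

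The rotated minus sham difference at stage 30 was higher for 11 than for 12 in the phenylalanine-tRNA synthetase gene farsa.S (1.30 ± 0.21, adjusted p = 0.0109), which passed whichever of the 20 libraries was left out. It was lower in ribosomal protein (adjusted p = 5.2e-16), immediate early (0 and 20 of 48 down), multiciliated cell, cement gland, stress and interferon genes (at most 0.0464), and higher in proliferation, notochord (0 and 1 of 26 up) and pan-neural genes (at most 0.0464). Only ribosomal protein genes still passed without the 3 libraries (8.1e-11). No list passed by estimated p (lowest 0.759). The test called 1 entry and DESeq2 58, 17.2% of them higher. The count was 3, 15 and 14 without sham 11 replicates 2, 4 and 5, 2, 26, 29, 26 and 32 without rotated 12 replicates 1 to 5, and 2 without sham 12 replicate 1.

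The rotated minus control difference was compared between the stages. For rotated 11 it was lower at stage 30 than at stage 18 in higd1a.S (-2.29 ± 0.44), abcb6.L (-1.71 ± 0.36) and the homeobox gene lhx1.S (-1.09 ± 0.23), and higher in prph.L (1.13 ± 0.20), farsa.S (0.99 ± 0.21) and the calcium-binding ocm (7.29 ± 1.34). For rotated 12 it was lower in upp1.L (-2.90 ± 0.45), tmem37.S (-2.60 ± 0.48), higd1a.S (-2.26 ± 0.44), pgam1.S (-2.24 ± 0.50) and p4ha2.L (-1.82 ± 0.37). It was higher in pgam2.L (2.35 ± 0.46), igsf10.L (2.36 ± 0.48), the muscle gene myoz2.S (2.02 ± 0.48), lect1.L (1.49 ± 0.36) and the inflammatory il1b.S (7.57 ± 1.52) and cxcl8.L (5.05 ± 1.12), the last 2 not passing without the 3 libraries. For rotated 11 forebrain and eye field (0 and 1 of 42 up, 0.000256), ribosomal protein, macrophage and ionocyte genes (at most 0.0359) were higher and neural crest lower (0 and 2 of 39 down, 0.000256) in this difference. For rotated 12 ribosomal protein (7.8e-16), muscle (2.4e-10), posterior hox, tailbud and notochord (at most 0.0270) and immediate early genes (2 and 13 of 50 up, 0.0275) were higher, and epidermis and multiciliated cell genes lower (at most 0.00611). Only ribosomal protein, muscle and multiciliated cell genes still passed without the 3 libraries (at most 0.0390), and immediate early genes were lower instead (0.0369). The lowest estimated p was 0.865 and 0.940.

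The stage difference called 13 entries for rotated 11 (5 higher, 85 by DESeq2) and 68 for rotated 12 (41 higher, 391 by DESeq2, 47.8% of them higher against 60.3% here and 51.6% with RLE). Of the named genes ocm and prph.L (11) and igsf10.L, pgam2.L, tmem37.S and upp1.L (12) passed whichever library was left out. The first count was 6, 6 and 7 without stage 18 control replicates 1, 2 and 5, 43 and 8 without stage 18 rotated 11 replicates 2 and 5, 6 and 7 without stage 30 control replicates 1 and 3, and 4 without stage 30 rotated 11 replicate 4. The second was 359 and 33 without stage 18 rotated 12 replicates 2 and 3, 121 without stage 30 rotated 12 replicate 4 and 12, 45, 37 and 124 without stage 30 control replicates 1, 3, 4 and 5.

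The anterior-posterior balance was scored per library. At stage 18 it was 0.276 ± 0.201 in control, -0.303 ± 0.436 in rotated 11, 0.064 ± 0.403 in transplant 11, -0.151 ± 0.18 in sham 11, 0.439 ± 0.096 in rotated 12, 0.393 ± 0.122 in transplant 12 and 0.579 ± 0.16 in sham 12 (log2 CPM, SD, n = 5 each). By exact permutation tests against control the unadjusted p was 0.0318 for rotated 11, 0.0238 for sham 11 and 0.0159 for sham 12. None of the 20 comparisons passed after adjustment (lowest adjusted p = 0.212), and none could have alone. At stage 30 it was 0.073 ± 0.28 in control, -0.15 ± 0.431 in rotated 11, -0.228 ± 0.173 in transplant 11, -0.038 ± 0.166 in rotated 12 and 0.243 ± 0.3 in transplant 12, with a lowest unadjusted p against control of 0.103 (exact permutation test, transplant 11).

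**Figure D5:**
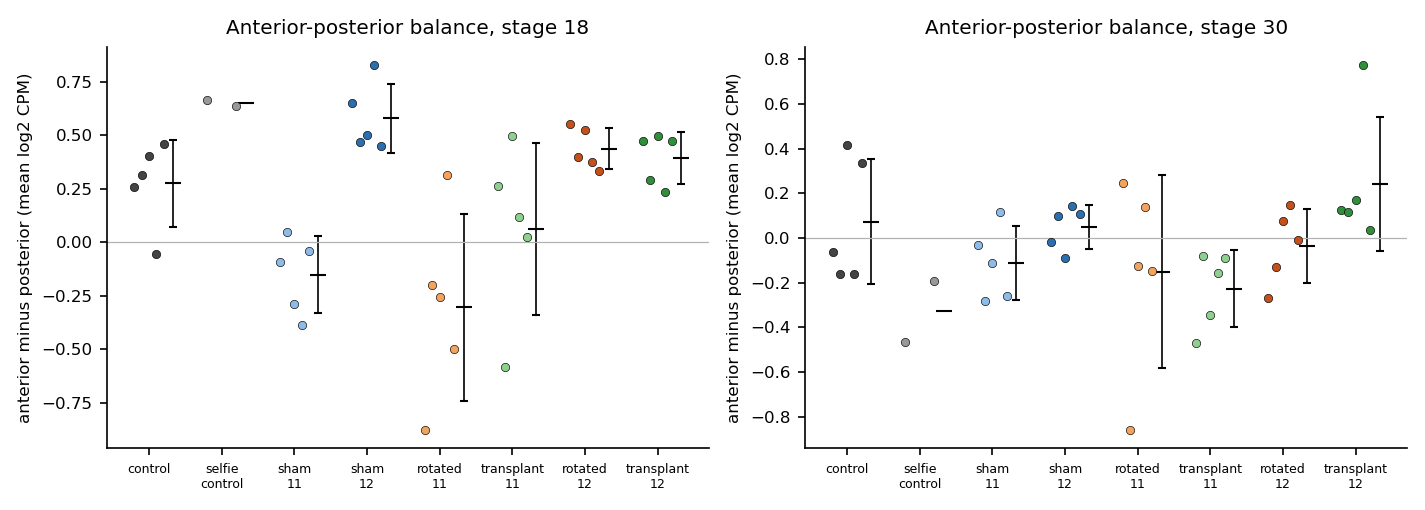
Anterior-posterior balance (log2 CPM) per library and group at both stages, with bars at the group mean ± SD (selfie control, n = 2, mean only).

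By the developmental stage score most surgery groups were closer to the younger stage than control. The score was -2.661 ± 0.094 in stage 18 control and -0.072 ± 0.166 in stage 30 control (log2 CPM, SD, n = 5 each). At stage 18 it was lower by exact permutation test in rotated 11 (-2.915 ± 0.136, adjusted p = 0.0272), transplant 11 (-3.012 ± 0.231, 0.0476), rotated 12 (-2.899 ± 0.089, 0.0159), transplant 12 (-2.902 ± 0.132, 0.0159) and sham 12 (-2.958 ± 0.056, 0.0159). At stage 30 it was lower in rotated 11 (-0.364 ± 0.123), transplant 11 (-0.359 ± 0.089) and sham 11 (-0.43 ± 0.164, exact adjusted p = 0.0159 for each). Sham 11 at stage 18 (exact adjusted p = 0.148) and rotated 12, transplant 12 and sham 12 at stage 30 (0.268, 0.944 and 0.229) did not pass. The shams are in the other library set. The call for transplant 11 at stage 18 was lost without any 1 of its replicates 2 to 5 or of the controls.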

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

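The splits and tests of explanations in this part were chosen after the results they measure were seen. The differences between numbers and stages were planned.

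In 30 of 350 sets of 5 libraries, 1 library lay far from the other 4, where chance gives about 1 in 20 (17.5). Values are CPM, with the range of the other 4 in brackets. Stage 30 rotated 12 replicate 1 had mmp8.L at 981 (0.163 to 1.06), cxcl8.S at 380.1 (0.131 to 0.706), socs3.L at 41.4 (0.392 to 1.49), socs3-like.1.L at 82.4 (5.92 to 6.86), cth.L at 258 (170.1 to 175), pcdh10.L at 4.14 (7.47 to 8.75) and mmp9.L at 84.3 (0.0979 to 0.513). Stage 18 sham 12 replicate 5 had gstp1.L at 379.5 (67.6 to 122), rps21.L at 9.58 (2.45 to 4.18), plk1.S at 235 (182 to 192) and rpl3.L at 2762 (1667 to 1732). Stage 18 rotated 11 replicate 5 had gclc.S at 36.7 (10.9 to 14.2), pir.L at 58.8 (28.02 to 31.6) and uck1.S at 32.4 (4.37 to 5.27). At stage 18 there were hebp2.L 4.17 (0.368 to 0.833) in control replicate 2, piwil3.L 7.14 (4.13 to 4.91) in control replicate 5, cdx4.L 47.0 (119 to 138) in rotated 12 replicate 1, tspan15.S 8.16 (3.203 to 4.26) in rotated 12 replicate 4, uck1.S 38.4 (3.81 to 5.16) in rotated 12 replicate 5, soat1.L 4.40 (2.58 to 2.95) in sham 12 replicate 1, lin7c.L 112 (35.9 to 43.9) in transplant 11 replicate 3, fos.S 12.8 (3.75 to 6.08) in transplant 12 replicate 3 and piwil3.L 0.494 (0.763 to 0.869) in transplant 12 replicate 5. At stage 30 there were cd37.S 7.96 (5.75 to 6.28) in control replicate 1, gad1.1.L 11.6 (17.5 to 19.9) in control replicate 2, actc1.S 412 (843 to 987) in control replicate 5, farsa.S 80 (58.4 to 63.0) in rotated 12 replicate 4, otog.L 2019 (2286 to 2393) in sham 12 replicate 1 and actc1.S 1184 (579.8 to 754) in transplant 12 replicate 5. The anterior-posterior balance of stage 30 transplant 12 replicate 4 was 0.773 (0.0350 to 0.168) in log2 CPM.

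Some entries passed a test of the difference itself. Of the 4 counts only rotated 11 between the stages exceeded every other split. Between numbers 11 and 12 the rotated minus sham difference differed in 4 entries at stage 18 (fdps.L 2.86 on the log2 scale) and in 1 at stage 30 (farsa.S 1.30). Between stage 30 and stage 18 the rotated minus control difference differed in 13 entries for rotated 11 (higd1a.S -2.29, abcb6.L -1.71, prph.L 1.13, lhx1.S -1.09, farsa.S 0.99 and ocm 7.29) and in 68 for rotated 12 (upp1.L -2.90, higd1a.S -2.26, p4ha2.L -1.82, pgam2.L 2.35, il1b.S 7.57, cxcl8.L 5.05, igsf10.L 2.36, myoz2.S 2.02, lect1.L 1.49, tmem37.S -2.60 and pgam1.S -2.24).

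Of 100 splits per comparison, the real one among them, the real count of entries called is given with the highest other count in brackets. Only 1 split, the real one, gave as many in the following, so a chance division of the libraries can be excluded at 1 in 100, with no allowance for the number of comparisons: against control at stage 18 rotated 11 = 34 (1), transplant 11 = 16 (1), sham 11 = 5691 (8), rotated 12 = 109 (6), transplant 12 = 169 (1), sham 12 = 9132 (640). Against sham at stage 18 rotated 11 = 3943 (81), transplant 11 = 4337 (68), rotated 12 = 9206 (2188), transplant 12 = 7561 (3088). Against control at stage 30 rotated 11 = 11 (7), sham 11 = 9445 (3784), sham 12 = 8380 (2219). Against sham at stage 30 rotated 11 = 6669 (831), transplant 11 = 5951 (1153), rotated 12 = 8670 (1882), transplant 12 = 7515 (1471). For the stage difference rotated 11 = 13 (6). Between the control stages = 21081 (14060). As many were given by 5 splits for rotated minus sham at stage 18, 4 (22), 7 splits for rotated 12 against control at stage 30, 203 (2297), 7 splits for transplant 12 against rotated at stage 30, 7 (235), 11 splits for rotated minus sham at stage 30, 1 (3) and 14 splits for rotated 12 for the stage difference, 68 (583), so chance cannot be excluded there. Where the real count was 0 nothing was tested, as all 100 splits give as many. These were rotated 11 against 12 at stages 18 (302) and 30 (560), and against control transplant 11 (527) and 12 (249) at stage 30. Against rotated they were transplant 11 (6) and 12 (1526) at stage 18 and transplant 11 (3) at stage 30. Splits that called several times the real count, as for rotated 12 against control at stage 30, point to a structure of the libraries other than the groups, which was not traced to any of them.

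Rotated and sham embryos differed in many genes at both stages. The labels of control and selfie control name no surgery, though they do not explain the selfie control. Rotation against sham as the whole cause is argued against, since the difference of control from selfie control accounts for most of the change. Once it is subtracted, the median log2 change of the called entries fell from 0.85 to 0.12 and 0.79 to 0.23 (rotated 11 and 12, stage 18) and from 0.56 to 0.1 and 0.57 to 0.17 (stage 30), with 13.7%, 29.7%, 17.1% and 30.3% left and 0, 1, 1 and 0 entries past the threshold, the smaller change and the 2 selfie libraries ending the calls. A difference in library size is argued against too, as 89.84% or more of the genes called in fits of the 2 groups alone still passed with every library thinned to 1 total. The library sets themselves do differ. At least 93.15% of the calls had the sign of control against selfie control. Of 695 genes called in selfie control against control at both stages, 692 had the same sign (214.1 shared genes expected by chance). Sham against control therefore does not measure sham surgery alone. What made the sets differ, which may be a preparation or sequencing batch that the labels do not give, stays open.

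In rotated 11 at stage 18 gstp1.L, pir.L, gclc.S and prdx1.L were higher than in control, with a median log2 change of 3.355 (1.915 in rotated 12, where only prdx1.L passed). Library size is argued against, as the highest rotated 11 total over the lowest control total is 0.26 on the log2 scale, under the smallest of the 4 changes (1.25). Rotation, going by the labels, is argued against as the whole cause, since their mean also rose in transplant 11 and transplant 12, by 2.93 (2.28 to 3.6, 95% interval by exact permutation) and 2.3 (0.66 to 3.64), against 3.27. Surgery of any kind may raise these genes and stays open, since they were also higher in sham 11 (2.785) and sham 12 (2.11) than in selfie control, but none passed there with 2 selfie libraries. A wider response of glutathione and oxidative stress genes stays open as well, the mean of the other genes of this kind giving an adjusted p of 0.127 (exact permutation test).

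Neuronal differentiation genes were lower than control at stage 30 in rotated 11, rotated 12 and transplant 11, which share their controls. The list did not pass with the correlation estimated (0.0834, 0.191 and 0.0994), and 1, 2 and 0 of 53 members passed over all entries. Estimates of the share due to a delay in development differ, so it stays open. A slope over single genes predicts changes of -0.063 (rotated 11), -0.07 (transplant 11) and -0.009 (rotated 12), leaving most of the fall. Once the stage score of each library is accounted for, changes of -0.138 of -0.304 in rotated 11, -0.157 of -0.319 in transplant 11 and -0.229 of -0.316 in rotated 12 are left in the list mean (exact permutation tests, p = 0.206, 0.175 and 0.0873). Low depth of 2 control libraries is argued against in rotated 11, where the list mean change of -0.3 became -0.28 without them (exact p = 0.0179). It stays open in transplant 11 and rotated 12, where -0.31 became -0.29 (exact p = 0.0357 and 0.0536, 5 against 3 libraries). Only rotated 11 had all libraries below every kept control. Surgery of any kind is argued against as the whole cause, since the list mean changed by 0.042 in transplant 12 (-0.192 to 0.284, 95% interval by exact permutation), which excludes the smallest fall of the 3 groups, -0.304. Rotation, going by the labels, is argued against as the whole cause by the fall of -0.319 in transplant 11 (exact p = 0.0159). An effect of rotation in the rotated groups, with another cause in transplant 11, stays open.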

How the results depend on the processing

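Fits without libraries that stand apart or of lowest total, selfie control in place of control, transplant against rotated and the subtraction were chosen after seeing the data. The other alternatives were planned. Of 220 named gene results none past the threshold changed direction when retested. The cause of the changes given here was not tested.

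Counts of entries that moved by over 1.5 times are given by alternative. With RLE size factors the count was against control at stage 30 rotated 12 = 120. Without the low-count filter they were against control at stage 18 rotated 11 = 22, transplant 12 = 110, against control at stage 30 rotated 11 = 7, rotated 12 = 29, for the stage difference rotated 11 = 8, against rotated at stage 30 transplant 12 = 0. With the stricter filter they were against control at stage 30 rotated 11 = 24, transplant 11 = 2, transplant 12 = 1, for rotated minus sham at stage 30 = 2, against rotated at stage 30 transplant 12 = 1. With the replicate number as a block they were against control at stage 30 rotated 11 = 33, rotated 12 = 97, for rotated 11 against 12 at stage 30 = 2, against rotated at stage 30 transplant 12 = 0. With only the groups compared they were against control at stage 18 rotated 11 = 63, transplant 11 = 31, sham 11 = 8586, rotated 12 = 24, transplant 12 = 393, selfie control = 5544, against sham at stage 18 rotated 12 = 3864, transplant 12 = 3736, for rotated minus sham at stage 18 = 1, against control at stage 30 rotated 11 = 0, rotated 12 = 0, selfie control = 1019, for the stage difference rotated 12 = 6, against rotated at stage 30 transplant 12 = 0. With DESeq2 they were against control at stage 18 rotated 11 = 193, transplant 11 = 223, rotated 12 = 447, transplant 12 = 595, for rotated 11 against 12 at stage 18 = 64, for rotated minus sham at stage 18 = 93, against control at stage 30 rotated 11 = 130, transplant 11 = 105, rotated 12 = 629, transplant 12 = 50, for rotated 11 against 12 at stage 30 = 418, for rotated minus sham at stage 30 = 58, for the stage difference rotated 11 = 85, rotated 12 = 391, against rotated at stage 18 transplant 11 = 5, transplant 12 = 6, against rotated at stage 30 transplant 12 = 123. Without the 3 libraries that stand apart they were against control at stage 18 rotated 11 = 166, transplant 11 = 343, rotated 12 = 268, transplant 12 = 753, selfie control = 4375, against sham at stage 18 rotated 11 = 6400, transplant 11 = 6984, for rotated 11 against 12 at stage 18 = 3, against control at stage 30 rotated 11 = 28, transplant 11 = 11, rotated 12 = 0, transplant 12 = 1, for rotated minus sham at stage 30 = 2, for the stage difference rotated 12 = 203, against rotated at stage 30 transplant 12 = 0. Without the 8 libraries of lowest total they were against control at stage 18 transplant 11 = 5, transplant 12 = 43, against sham at stage 18 transplant 11 = 2790, for rotated 11 against 12 at stage 18 = 1, for rotated minus sham at stage 18 = 2, against control at stage 30 rotated 11 = 0, rotated 12 = 365, transplant 12 = 13, for the stage difference rotated 12 = 103, against rotated at stage 18 transplant 11 = 1, against rotated at stage 30 transplant 12 = 0. With selfie control in place of control they were sham 11 = 10, sham 12 = 2 at stage 18. At stage 30 they were sham 11 = 1, sham 12 = 0. With the control and selfie control difference subtracted the counts were against sham at stage 18 rotated 11 = 0, transplant 11 = 0, rotated 12 = 1, transplant 12 = 2, and against sham at stage 30 rotated 11 = 1, transplant 11 = 2, rotated 12 = 0, transplant 12 = 0. Of the named genes 9, 41, 2, 34, 77, 0, 37 and 53 no longer passed under the first 8 of these in turn.

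With 1 library left out at a time, 116 counts moved by over 1.5 times and 248 did not. Of the tests of named genes in such fits, 1725 gave the same call, 622 lost it and 1 gained it. The counts ranged as follows: against control at stage 18 rotated 11 = 17 to 84, transplant 11 = 3 to 155, rotated 12 = 16 to 319, transplant 12 = 38 to 304, selfie control = 251 to 2317, for rotated 11 against 12 at stage 18 = 0 to 8, for rotated minus sham at stage 18 = 2 to 33, against control at stage 30 rotated 11 = 0 to 33, transplant 11 = 0 to 2, rotated 12 = 0 to 987, transplant 12 = 0 to 37, selfie control = 380 to 2971, for rotated 11 against 12 at stage 30 = 0 to 518, for rotated minus sham at stage 30 = 1 to 32, for the stage difference rotated 11 = 4 to 43, rotated 12 = 12 to 359, against rotated at stage 18 transplant 11 = 0 to 1, against rotated at stage 30 transplant 12 = 0 to 206.

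List tests depended most on the correlation between genes. With the correlation estimated, 2 of 222 calls held, 1 each for tailbud and posterior signals and axis patterning signals. The total was 220 with the replicate number as a block, 223 with RLE and 165 with the .L and .S copies summed. Of the 128 list results followed through the alternatives, none with sham or selfie control, 126, 3, 3 and 38 no longer passed under these in turn, and none changed direction. The 55 that involve a library that stands apart were also tested without such libraries, where 22 no longer passed and 11 more changed direction (adjusted p in brackets): pan-neural (0.02182) and notochord (0.1129) for rotated 12 against control at stage 18, pan-neural (0.4668), midbrain (0.9763) and notochord (0.4874) for rotated 11 against 12 at stage 18, immediate early (0.5837) for rotated 12 against control at stage 30, immediate early (0.02557) for rotated 11 against 12 at stage 30, posterior hox (0.8558), tailbud (0.398), notochord (0.4496) and immediate early (0.03688) for rotated 12 between the stages. List tests were not repeated without other single libraries. With copies summed the number of comparisons a list passed in fell by over 1.5 times for pan-neural 8 to 2, hindbrain 6 to 2, placodes 1 to 0, photoreceptors 2 to 1, ionocytes 2 to 0, cement and hatching gland 3 to 1, notochord 12 to 7, blood 5 to 0, endoderm 8 to 5, immediate early 10 to 3, interferon 2 to 1 and hypoxia 1 to 0.

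The stage score kept its direction but no longer passed in 8 comparisons with control when libraries were paired by replicate number, at -0.255 (rotated 11), -0.351 (transplant 11), -0.238 (rotated 12), -0.241 (transplant 12) and -0.297 (sham 12) at stage 18, and -0.291 (rotated 11), -0.287 (transplant 11) and -0.358 (sham 11) at stage 30 (exact adjusted p = 0.107 to 0.188). This pairing can give no p under 0.0625 before adjustment. The numbers were not taken to pair the libraries, as in 1 of 42 pairs of groups, both of stage 30, were all correlations of libraries with the same number over 0.1. Yet among the control, rotated and transplant groups the mean correlation was 0.126 at stage 30 (p = 0.0001 by shuffling the numbers, tested after seeing the data) and 0.01 at stage 18 (p = 0.671), so at stage 30 libraries of 1 number deviated together, which unpaired tests leave out. With a median in place of the mean the stage score of transplant 12 at stage 30, not past its test, changed sign to 0.004. With 1 library left out the scores whose call or sign changed ranged as follows: balance of sham 12 against control at stage 30 -0.084 to 0.06 (reversed: 0.01 without sham 12 replicate 3, 0.06 without control replicate 3, 0.041 without control replicate 5), balance of rotated 11 against sham 11 at stage 30 -0.136 to 0.14 (reversed: 0.14 without rotated 11 replicate 2, 0.021 without sham 11 replicate 4), developmental stage score, stage 18, transplant 11 against control, -0.439 to -0.283, stage score of sham 11 against control at stage 18 -0.266 to -0.138 (past its test without sham 11 replicate 4, exact adjusted p = 0.0238), stage score of transplant 12 against control at stage 30 -0.059 to 0.072 (reversed: 0.014 without transplant 12 replicate 3, 0.072 without transplant 12 replicate 5, 0.003 without control replicate 2, 0.053 without control replicate 4). The prior count and RLE changed no call of a score.

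Thinning for depth is given above.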
